A study of Mus musculus with 8 samples.

How the data were processed

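RNA from mouse dorsal root ganglion co-cultures was amplified, biotin-labelled and hybridised to Illumina mouse bead arrays, per the labels' protocols. Slips were taken in triplicate at each of 8 time points, which makes 24 arrays on 3 chips of 8. The deposited values are probe intensities, given as average signal per probe, and BeadStudio is named in the submitters' processing notes. The experiment settings state that no normalization was applied, per the file headers. Background had been subtracted, since a share of the values lies below 0. The table gives 1 value per time point; how the 3 arrays were combined is not given in the sources used here, and single arrays were not used here. The series matrix holds the same intensities as the deposited table, with 0 cells that differ, so centring and scaling are those of that table. A text that accompanies the data gives the arrays of 48 h a range overlapping that of 36 h; the ranges in the sample labels, which do not overlap, were used.

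Intensities were offset by 50, put on the log2 scale and quantile normalized with limma 3.58.1 in R 4.3.3. The offset shrinks the changes of dim probes. No detection p was used, so a probe counted as detected at a time point when its signal lay above the median of all probes there. Probes detected in at least 3 time points were tested, 12886 of 24611. The trend was a limma fit with a mean-variance trend on log2 of hours plus 1, reported as the fitted change from 0 to 48 h. The phase comparison was a limma contrast of 3 late against 3 early time points, with 6 and 12 h as a group of their own. Both are two-sided with Benjamini-Hochberg adjustment at 0.05. Each later time point was set against 0 h by the count of probes changed at least 2-fold, without a test. A test over all time points, planned for single arrays, was not run. Groups came from the labels, and the tests, gene lists and most alternatives were fixed before the data were examined.

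The fits were tested on simulated data, with 8 values per probe drawn from the real means and scatter of 12886 probes and 200 probes given a known trend. The trend fit recovered 52% of changes of 0.5, 88% of 1, 98% of 2 and 100% of 3 on the log2 scale, with 7 false calls among 176. The phase contrast recovered 36%, 84%, 96% and 100% of the same simulated trends, with 3 false calls among 161. Their sizes are changes from 0 to 48 h, and the difference between the phases is smaller. The rates of the 2 fits are therefore not like for like. The simulated scatter was drawn independently for each probe and time point, with no chip difference and no drift shared by neighbouring time points. These rates therefore do not carry over to real fits where such effects are present.

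Probes were named through the platform annotation, and symbols were matched by Entrez identifier to the RefSeq gene table for 20966 probes, which changed 0 of them. It lists 1 symbol for 20982 probes and several for 1, and 3628 probes are unnamed here. The rule for named genes, fixed in advance, took the 10 largest fitted rises and 10 largest falls, the 3 largest rises and falls at each time, up to 4 members of each list, and 10 genes always. Since signal did not follow the names, the rule's symbols are not printed. The 2 largest rises and 2 largest falls that meet it are given by probe identifier. The 24 lists were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry, which called 11; 419 of the 477 listed genes have a probe. Names were compared with signal in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

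Alternatives covered the offset, the normalization, the filter, the table used, the chip shares, the time scale, the baseline, the phases, the choice of probe per gene and leaving out each time point. Cyclic loess, leaving out both 1 h and 24 h, and a threshold of 1.5-fold were added after seeing the data.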

Results

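The series followed mouse co-cultures of Schwann cells and sensory neurons through the first 48 h of maturation. The cells came from dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, taken from wild-type embryos. Schwann cells are the glia that wrap and myelinate peripheral axons. Ascorbic acid, which such cultures need to form a basal lamina and then myelin, was added at 0 h. RNA was taken at 0 h, at 0.5 and 1 h, at 6 and 12 h, and then every 12 h to the end, from 3 culture slips each time, and measured on 24 bead arrays. The table analysed here holds 1 value per probe and time point, for 24611 probes, so no value has a spread between slips. Mean signal ran from 317 at 6 h to 448 at 0.5 h. Between 28.2% and 33.8% of the values of a time point lay below 0 after background subtraction. The number of time points, not of slips, limits the precision of every test of change over time below.

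The arrays lay on 3 chips of 8, in the order of the time points. By the sample numbers in the labels, 0 and 0.5 h lay on the first chip, 6 and 12 h on the second, and 36 and 48 h on the third. The arrays of 1 h were split 2 to 1 between the first and second chips, and those of 24 h 1 to 2 between the second and the third. Time and chip therefore move together through most of the series.

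Gene names could not be attached to the signals. In most tissues, ribosomal protein transcripts are abundant and most olfactory receptor genes are silent. The same was assumed of these cultures, and the former were set against the latter. Probes were taken as ribosomal protein probes when their symbol started with Rpl or Rps and a digit. That pattern can also take in kinases named after a ribosomal protein, and misses a few ribosomal protein genes. How many such kinases it took in was not counted, so the set may be mixed. The 73 probes with such a name had a median signal percentile of 50.7 (quartiles 21.2 and 80.2) among all probes. The 1007 probes annotated to olfactory receptor genes had a median percentile of 48.6 (quartiles 24.1 and 75.6). Above the 90th percentile lay 9 of the ribosomal protein probes and 106 of the olfactory receptor probes. Pairs of probes with the same transcript accession should share a level, yet over 6097 such pairs Spearman's rho across probes was 0.108. With signals shuffled 1000 times, rho ran from -0.040 to 0.039. Across the 24 gene lists, the median percentile of a list's probes ran from 31.1 for endothelial cells to 74.9 for the unfolded protein and amino acid response. The SD of these medians was at least as large in 662 of 1000 shuffles, the highest median at least as high in 176, and the lowest at least as low in 550. Single probes went both ways in examples chosen after their values were seen. The probe annotated to Mbp, a major myelin protein, had a mean signal of 22086, and the 4 annotated to Actb, a cytoskeletal actin, had means from 5.39 to 150. Probes are therefore given by identifier, and no change below is assigned to a gene.

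**Figure D1:**
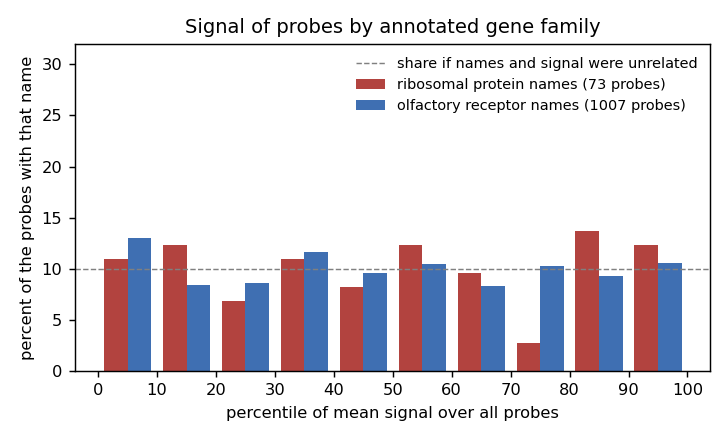
Bars give the percent of probes with a ribosomal protein name (red, 73 probes) and with an olfactory receptor name (blue, 1007 probes). The bins are 10 equal parts of the ranking of all probes by mean signal over the 8 time points. The horizontal axis gives the percentile. Ribosomal protein names are symbols that start with Rpl or Rps and a digit, which can include kinases named after a ribosomal protein. The dashed line at 10% is the share expected if name and signal were unrelated, and both families lie around it.

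The first comparison asked how the transcriptome moved away from its state at ascorbic acid addition. Few probes had changed within 1 h, many more had by 6 h, and the counts were higher again by 36 h. At 0.5 h, 3 of 11724 probes detected at both times were at least 2-fold higher than at 0 h and 9 were at least 2-fold lower. At 1 h, 31 were higher and 7 lower. The counts rose to 198 higher and 261 lower at 6 h, and to 231 and 312 at 12 h. At 24 h, 309 probes were higher and 277 lower. At 36 h the counts were 428 and 381, and at 48 h they were 456 and 353, of 11488. The SD of the log2 difference from 0 h over probes was 0.20 at both 0.5 and 1 h, 0.44 at 6 h, 0.48 at 24 h and 0.56 at 48 h. These are differences between single values with no replicate check, so no p is given. With an offset of 16 in place of 50, and negative values set to 0, 34 probes changed at 0.5 h and 902 at 24 h.

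**Figure D2:**
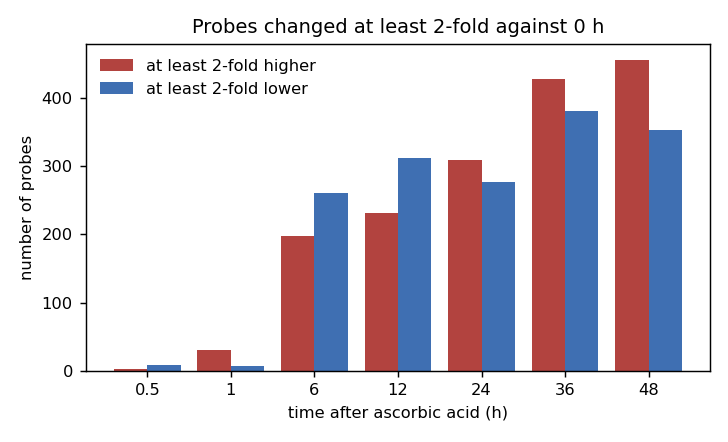
Bars count the probes at least 2-fold higher (red) or lower (blue) than at 0 h, against hours after ascorbic acid, among probes above the median signal at both times. There is 1 value per time point and so no error bar; the counts pass from 31 higher and 7 lower at 1 h to 198 and 261 at 6 h.

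The amount of change differed between intervals, which are of unequal length; that from 1 to 6 h is the widest on the log2 scale of hours plus 1. Of 1550 probes whose log2 signal spanned at least 1 over the series, 717 made their largest step between 1 and 6 h, 278 of them upward and 439 downward. Another 405 made it between 24 and 36 h, 234 upward and 171 downward. Within the first hour, the step from 0.5 to 1 h was the largest for 144 probes. Among the 12886 probes of the trend test, a set other than that counted against 0 h, 13 differed at least 2-fold from 0 to 0.5 h, 45 from 0.5 to 1 h, 283 from 1 to 6 h, 14 from 6 to 12 h, 15 from 12 to 24 h, 121 from 24 to 36 h and 8 from 36 to 48 h. The first principal component held 65.8% of the variance and ordered the time points by hour. The second, with 18.2%, set 6, 12 and 24 h apart from the earlier and later ones. These 3 also had the lowest mean signal before normalization, 317, 324 and 336, while the others ran from 360 to 448. Whether this component follows signal strength was not tested. The means of 0 to 1 h, of 6 and 12 h, and of 36 and 48 h were then compared, with a difference of 1.5-fold counted as a change. By that measure 565 probes were lower by 6 and 12 h and then level, 385 were higher and then level, 321 were level and then higher, and 195 level and then lower. Another 140 were higher and then higher again, and 39 higher and then lower. After a fall, 85 probes were then higher and 46 lower again.

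**Figure D3:**
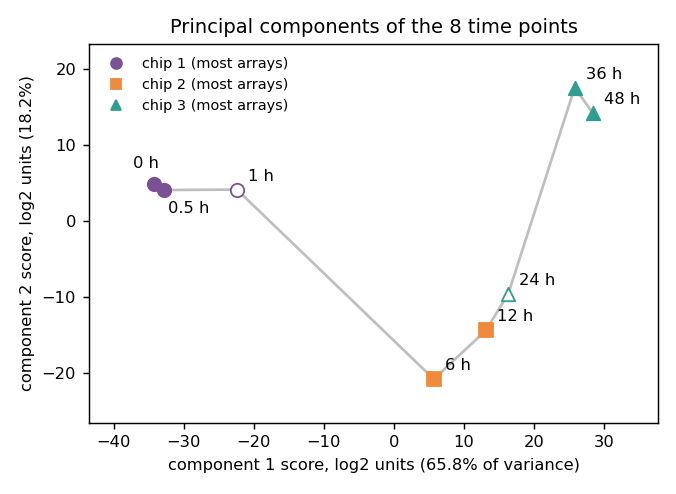
Each point is a time point, placed by its scores on the first and second principal components of the log2 signals (65.8% and 18.2% of the variance), and the line joins them in order of time. Marker shape and colour give the chip that held most of its arrays, and white markers are 1 h and 24 h, whose arrays lay on 2 chips; 24 h sits beside 12 h.

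The second comparison asked which probes followed a trend with time. A line on log2 of hours plus 1 was fitted to 12886 probes with limma, and 3859 passed an adjusted p of 0.05. Of these, 1820 rose and 2039 fell, so that 47.2% rose. That share depended on the processing. It was 37.8% without normalization, 44.4% with median scaling, 52.0% on linear hours and 52.1% with cyclic loess. The median size of the fitted change from 0 to 48 h was 0.63 on the log2 scale (quartiles 0.45 and 0.98). At least a 2-fold change was fitted for 524 rising and 413 falling probes. ILMN_2616872 had a fitted rise of 5.28 on the log2 scale (SE 0.66, limma adjusted p = 0.000338). Its signal was -5.6 at 0 h, 336 at 1 h, 871 at 24 h, 2693 at 36 h and 2090 at 48 h. As its signal at 0 h is below background, the size depends on the offset. It was 6.45 with an offset of 16 and negative values set to 0. ILMN_2649548 rose by 5.06 (SE 0.45, limma adjusted p = 6.38e-05), from a signal of 7.9 at 0 h to 2664 at 36 h and 1940 at 48 h. It too was not detected at 0 h, so its size also depends on the offset, and was 6.12 with an offset of 16. ILMN_2773348 fell by 4.47 (SE 0.55, limma adjusted p = 0.000307), from 1738 to 40.2. ILMN_1254042 fell by 4.37 (SE 0.47, limma adjusted p = 0.000165), from 1943 to 85.5, and stood at 122 by 6 h. The error in this fit is the scatter of 8 single values about a line, so that it holds any curve in the response as well as noise. With the share of each time point's arrays on each chip in the fit, limma called 0 probes (381 at an unadjusted p under 0.05). The SE of the change was then 6.29 times as large at the median. The changes of ILMN_2616872 and ILMN_2649548 turned to -1.23 and -0.26, but neither was called (limma adjusted p = 0.999861 for both), so no fall is shown. Over all tested probes, the changes with and without chip shares had a Spearman rho of 0.357. Errors this much larger can lower the rho by themselves. The count of called probes was 2468 without 0 h, 2559 without 1 h and 24 h, and 2273 on linear hours.

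The third comparison set the late time points, 24, 36 and 48 h, against the early ones, 0, 0.5 and 1 h. limma called 4261 of 12886 probes, 1976 higher and 2285 lower in the late phase. The median size of the difference was 0.50 on the log2 scale, and it was at least 2-fold for 395 probes that were higher and 270 that were lower. The 3 time points of a phase stood in for replicates here, although they share real change. Both this test and the trend called 3675 probes, each in the same direction, where independent lists of these sizes would share 1276; the 2 tests use the same values and are not independent. With the chip shares in the fit, limma called 24 probes (1022 at an unadjusted p under 0.05). The SE was then 5.61 times as large at the median. Over all tested probes, these differences had a Spearman rho of 0.020 with the reported ones, so their order was not kept. The larger errors could scatter the order by themselves, so this rho cannot show whether the chips made the differences. Without 0 h, 2806 probes were called. With 36 and 48 h as late and 0 and 0.5 h as early, 2669 were called.

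The 24 gene lists fixed in advance were tested on the trend by the names in the annotation, although those names did not follow the signal. limma's camera, with a preset correlation of 0.01, called 2 of the 24. With chip shares in the fit it called 0, and with median scaling or no normalization it called 1. Among 15 measured probes named for the unfolded protein and amino acid response, 7 rose and 0 fell, with a median change of 0.37 and an adjusted p of 0.000829; 7 passed when adjusted over the list alone. Among 7 named for smooth muscle and pericytes, 0 rose and 4 fell, with a median change of -0.41 and an adjusted p of 0.0426; 5 passed when adjusted over the list alone. Both calls were lost with an estimated correlation, at adjusted p = 0.269 and adjusted p = 0.354 respectively. Shuffling the names over the probes 100 times gave any call in 3 shuffles, and never more than 1. Of all probes named in the lists, 28.5% changed with time, against 29.9% of all probes tested. limma's fry called 11 of the 24 lists. The unfolded protein list and the smooth muscle and pericyte list were among them, each at a fry adjusted p of 0.000837. Unlike camera, fry asks whether a list changed at all, not whether it changed more than other probes. Where so many of all probes are called, its calls do not set a list apart.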

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

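Of 262 values of 15 results under 24 alternatives, 236 kept their direction and side of the threshold or stayed within 1.5 times the reported count, 22 moved, 2 became weaker and 2 reversed. Cyclic loess, the series without 1 h and 24 h, and the threshold of 1.5-fold were chosen after seeing the data. With chip shares as a covariate, the trend called 0 probes and so 0% that rose, the phase comparison 24 and the lists 0. ILMN_2616872 then changed by -1.23 and ILMN_2649548 by -0.26, against rises otherwise. These are the 2 values that reversed, and neither was called (limma adjusted p = 0.999861 for both). The falls of ILMN_1254042 (-4.40) and ILMN_2773348 (-4.94) were no smaller than reported, and lost their calls through larger errors. Over all tested probes, the estimates with chip shares had a Spearman rho with the reported ones of 0.357 for the trend and 0.020 for the phases. The chip shares follow time closely and leave 4 residual degrees of freedom for the trend and 3 for the phases. Larger errors alone could scatter the estimates in this way, so the rhos cannot show whether the chips account for the changes. The trend called 2273 probes on linear hours and 2559 without 1 h and 24 h; leaving out 1 time point gave 2468, without 0 h, to 4269. The phase comparison gave 2669 with late as 36 and 48 h and early as 0 and 0.5 h, and 2806, without 0 h, to 4467 with 1 time point left out. Lists called fell from 2 to 1 with median scaling, no normalization, or without 1 h and 24 h, and ran from 1 to 2 with 1 time point left out. With an offset of 16 and negative values set to 0, 34 probes changed 2-fold at 0.5 h and 902 at 24 h. At 1.5-fold the counts were 156, 170, 1330, 1552, 1676, 2040 and 2039 in order of time. Apart from the chip shares and the fewer time points, the cause was not tested. The series matrix moved nothing, being the same values. The 2-fold counts do not use the filter on dim probes, so the filter alternatives could not move them. Leaving out a time point other than those compared reaches these counts only through the normalization. The 236 values that held therefore include some that could not move or could hardly do so. Chip as a random block, the test over all time points and fits of 2 groups need single arrays and were not run; the 2-fold counts have no value with chip shares, or against 0 h with 0 h left out. No paired analysis was possible because each time point has 1 value. Signal near background limits the dimmest probes, where the offset sets the change.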

Other observations

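Every test in this part except the reorderings of time points was chosen after the values were seen, and 4 were changed again once their first outcome was known, as said at each.

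The first pattern is that gene names do not follow signal. Ribosomal protein names lay only 2.11 percentile points above olfactory receptor names at the median; this restates the pattern, and cannot tell displaced probe identifiers from a wrong annotation, so both stay open. Noise in dim signal that scrambles the ranking is argued against, since the ranking of all probes held between time points at a Spearman rho of at least 0.952. A background particular to each probe would also repeat between time points, so this cannot show that the ranking follows transcript amounts. A constant shift of the rows gave at most 15.4 percentile points over 49222 shifts; this missed the bound of 15 first set for excluding it, and a comparison then added placed it within the 12.8 to 19.6 points of 200 shuffles, so one test leaves a shift open and the later one argues against it. For an annotation made for another array version, 85.3% of identifiers are listed, which does not show that the listed genes are right; no biological explanation was tested. Some link remains, since the levels of 6097 same-accession pairs had a rho of 0.108, beyond the -0.040 to 0.039 of shuffled signals. Any mismatch may therefore be incomplete. The trends of 1828 such pairs had a rho of 0.090 (shuffled -0.079 to 0.083). That shuffle reordered pairs, not probes, and a probe can be in several pairs, so its range may be too narrow and this rho decides little.

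The second pattern is the larger change between 1 and 6 h, where 2 of 3 arrays change chip, and between 24 and 36 h, where 1 of 3 does; between 12 and 24 h 2 of 3 do, yet the SD of the log2 difference was 0.19 there and 15 probes differed 2-fold. The prediction for a chip difference put 24 h at 0.667 of the way from 6 and 12 h to 36 and 48 h. It assumes that the chips made the whole step and that the 3 arrays were averaged on the linear scale. But 181 rising probes had a median of 0.178 (quartiles 0.073 and 0.323) and 31 falling ones 0.385 (quartiles 0.246 and 0.523). This argues against a step made wholly by the chips, if the array numbers and the averaging hold. A chip difference mixed with real change could give another fraction, so it stays open. At 1 h the prediction of 0.333 lay just beyond the quartiles of rising probes (median 0.233, quartiles 0.151 and 0.329) and within those of falling ones (0.045 and 0.440); the rule was tightened to need both, so a chip effect there stays open. For smooth change, the median SD of neighbours whose arrays partly share a chip was 1.31 times that of neighbours on 1 chip, which decides nothing, as no neighbours lie wholly on different chips; a second test, added after that ratio was seen, put the 24 to 36 h step at 1.64 times the larger of the 12 h steps beside it, but this restates the pattern and has no spread between slips behind it, so smooth change stays open. The SD from 12 to 24 h was 0.907 times that from 6 to 12 h, as misplaced 24 h arrays could give. All 3 on the second chip would need 9 arrays on a chip of 8. With 2 of 3 there, against the labels, 24 h would lie at 0.333. That is just beyond the quartiles of rising and within those of falling probes (a check added after the ratio was seen). With the 1 array of 1 h that the labels put there, 2 of 3 would overfill the second chip too. Misplaced 24 h arrays alone therefore exceed the places, but a misplacement that also moved an array of another time point stays open. So does a real late response, which was not tested.

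Chance as the source of the trend was tested by reordering the time points. Only 1 of 100 orders, the real one with 3859 probes, gave as many, and the highest other gave 2773. This argues against a random order of the values. Reordering treats the time points as interchangeable, so it cannot tell a response to ascorbic acid from any other change that runs with time. For the phases, the real split gave 4261 probes and the highest of the others 0, but 10 splits are too few for a share under 0.05. Only 1 split, the real one, gave as many. Each other split mixes early with late time points, so the difference between them becomes scatter. Few calls would then follow whatever made that difference, and the contrast of 4261 with 0 decides little. Neither count bears on the chips, which follow the same order.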
